A study of Mus musculus with 3 samples.

How the data were processed

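The series holds 3 libraries of mouse hind paw cells in K/BxN serum transfer arthritis, made with the 10x 3' single-cell kit: sorted CD45-negative cells at steady state (stromal day 0) and at day 5 (stromal day 5), and sorted CD45-positive, CD11b-positive, Ly6G-negative cells at day 9 (myeloid day 9). Per the labels, skin, muscles and tendons were removed, and the tissue was digested with collagenase IV and DNase before sorting. The authors made the deposited UMI counts with Cell Ranger 6.0.1 per the file headers, from reads aligned to the 10x mm10 reference, and kept only barcodes called as cells. The labels also name Seurat, without stating its role in these files. The values are whole numbers, and the lowest total per barcode was 513 at day 0 and 500 at days 5 and 9. Raw reads were not analysed here. Gene coordinates are from the GENCODE annotation of mm10.

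Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which left 7368, 11172 and 5945 of the 7740, 11900 and 7795 barcodes. Scrublet marked 1, 0 and 1 cells, under the set minimum of 0.5%, so the barcodes with the highest Scrublet scores were removed at 0.8% per 1000 barcodes, as fixed before the data were examined. This removed 461, 1073 and 390 of the passing cells. Doublets of 2 cells of a similar type can remain. Counts were log-normalized to 10000 UMIs per cell, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 were used. The stromal libraries were clustered together without batch integration, the myeloid library alone, and the fibroblasts again at resolution 0.5. Clusters were named from 36 fixed marker lists. A name needed at least 3 markers detected, at 20 CPM and in 10% of cells, and was checked against the 10 genes leading the cluster by fold, with 10 CPM added. A small stromal cluster of mixed cells was split further before naming. Names rest on RNA alone, which "like" marks where a class is introduced, and short names are used after that.

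UMIs were summed over the cells of a class in each library and divided by the class total to give CPM. Shares carry Clopper-Pearson intervals, CPM exact Poisson intervals and ratios the exact conditional binomial interval, all at 95%. Cells are not replicates, so no test was run with 1 library per group. A gene with 0 counts in a library was given a bound from 3 counts. Named genes had at least 50 CPM in the higher library and at least 50 counts over both, and were not under 10% of their CPM in another class of at least 50 cells. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor, predicted and listed sex-linked genes were left out. The 12 genes with the largest ratio in each direction were taken in fibroblasts, and 5 in each direction in other classes and subsets with at least 100 cells per library. From each list, 2 members in the direction of its median and 1 in the other were taken. In the myeloid library, list genes differing at least 5-fold between classes and the 3 members of highest level were taken. Further genes of the lists and of the pairs are given as examples chosen after their values were seen. A difference of 1.5-fold is used as a size, not as a call.

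There were 16 gene lists for fibroblasts, tenocytes and osteoblasts, 2 for endothelial cells, 1 for mural cells, 4 for macrophages and 6 for RNA of other cells, and 28 ligand and receptor pairs. Members with at least 20 counts were used. Each list median was placed among 10000 random lists of the same size drawn from 20 expression bins. The lists of sterol and clock genes, the comparison within each tenocyte cluster and the bounds on fibroblast RNA in other droplets were added after the data were seen.

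Alternatives set before the data were examined were a looser filter (200 genes, 20% mitochondrial UMIs), a stricter filter (1000 genes, 2000 UMIs, 5%), no doublet removal, resolutions of 0.5 and 2.0, a fibroblast resolution of 1.0 and each stromal library clustered alone. For gene levels they were DESeq2 median-of-ratios and edgeR TMM scaling, the mean of each cell's CPM, cells thinned to 2000 UMIs, cells without UMIs of Ptprc, S100a8 and S100a9, equal weight for sub-clusters with at least 50 cells in each library, and no count minimum with 0.5 added. Chosen after seeing the data were clustering without differing genes, fibroblasts without sub-clusters 4 and 13, and fibroblasts with sub-cluster 12.

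The method was tested on simulated sums with 200 changed genes. Both libraries were drawn as Poisson counts from a shared profile per class, with no variation between cells, animals or libraries. The rule on levels in other classes was not applied. This checks the computation and counting error only, not differences between libraries. At 1.5-fold, the right direction was found for 67 of 67 genes in fibroblasts, 66 of 67 in tenocytes and 64 of 67 in osteoblasts, and the true fold lay in the interval for 66, 65 and 66. At 2-fold it lay there for 63, 66 and 64 of 67, and at 4-fold for 61, 62 and 65 of 66. All 24, 10 and 10 genes named there were changed genes. Of 200 unchanged lists, 10, 13 and 8 lay outside the central 95% of random lists. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with DESeq2 1.42.0 and edgeR 4.0.16.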

Results

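Single-cell RNA sequencing was done on cells from the hind paws of mice in K/BxN serum transfer arthritis, a model in which transferred serum with autoantibodies starts a joint inflammation that later resolves. There were 3 libraries, 1 per group. Stromal day 0 and stromal day 5 held sorted CD45-negative cells, the non-leukocytes of the joint, at steady state and 5 days after serum. Myeloid day 9 held sorted leukocytes that carried CD45 and CD11b and lacked the neutrophil marker Ly6G. The series was set up to add time points to earlier single-cell data of the same model. The count tables held 77842586 unique molecular identifiers (UMIs, each standing for a captured RNA molecule) in 7740 barcodes at day 0, 122224428 in 11900 barcodes at day 5 and 69430907 in 7795 barcodes at day 9. After cell filters and doublet removal, 6907, 10099 and 5555 cells were kept, with medians of 9681, 9124 and 6389 UMIs per cell. There were no replicates, so no test was run: the 95% intervals cover counting error only, and the day cannot be told apart from the library. The labels do not state how many mice each library holds, so animals cannot be told apart either. Levels are given as CPM, the counts of a gene per 1000000 UMIs summed over a class of cells in a library. Shares carry exact binomial (Clopper-Pearson) intervals, and ratios of CPM carry exact conditional ones.

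The stromal pair asks how the connective tissue cells of the paw differ between steady state and day 5 of arthritis. Fibroblast-like cells, named by collagen genes, Dcn and Pdgfra, made up most of both libraries, at 76.7% of cells at day 0 (5296 of 6907, 75.7 to 77.7) and 81.6% at day 5 (8241 of 10099, 80.8 to 82.4). Tenocyte-like cells (Tnmd, Fmod, Thbs4) made up 13.02% at day 0 (12.2 to 13.8) and 10.9% at day 5 (10.3 to 11.5). Osteoblast-like cells (Bglap, Ibsp, Alpl) made up 7.85% (7.22 to 8.51) and 5.82% (5.37 to 6.30). Blood endothelial-like cells were 85 cells, or 1.23%, at day 0 and 36 cells, or 0.356%, at day 5. Chondrocyte-like cells were 45 and 18, mural-like cells 15 and 19, muscle satellite-like cells 5 and 12, and lymphatic endothelial-like cells 9 and 1. Unnamed cells were 11 at day 0 and 82 at day 5. They included 2 small clusters led by skeletal muscle genes, and 49 cells of fibroblast sub-cluster 12, all from day 5, kept out of the fibroblast class after the data were seen because osteoblast genes were among those that led it. The digestion and the CD45-negative sort set which cells were loaded, so these are shares of sorted cells and not of the tissue. Per the labels, tendons were removed before digestion, so tissue of the tenocyte-like cells should have been taken away, and their share also depends on that dissection. Fibroblast clusters 1 and 7 had none of the fibroblast markers and 1 leukocyte marker each among their 10 leading genes (Hp, from the monocyte list, and Lcn2, from the neutrophil list), and all 7 fibroblast markers were detected in both. The largest fibroblast clusters differed between the days. They were clusters 0 and 4 at day 0, with 983 and 878 cells, and clusters 7, 2 and 1 at day 5, with 1113, 1058 and 1056 cells. Among tenocytes, cluster 3 was the largest on both days, with 684 cells at day 0 and 599 at day 5, and cluster 11 held 215 and 503.

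Among fibroblasts, a state led by acute-phase and chemokine genes was found almost only in the day 5 library, and a progenitor-like state took a lower share there. Fibroblasts were clustered for this without the genes that differed at least 1.5-fold between the libraries, a choice made after the data were seen. The cluster led by Saa3, Ptx3 and Ccl2 then held 0.680% of fibroblasts at day 0 (36 cells, 0.477 to 0.940) and 17.1% at day 5 (1411 cells, 16.3 to 17.95). The progenitor-like cluster, with Pi16 and Dpp4 of adventitial fibroblasts, held 16.9% (15.9 to 17.9) and 6.97% (6.42 to 7.54). A cluster led by Igfbp6, Thbs2 and Tnmd held 19.8% and 12.6%, and a cluster led by Rrad, Phex and Atf3 held 13.5% and 7.79%. The cluster led by Hand2os1 held 13.1% at day 0 and 20.1% at day 5. The lining-like cluster, with Prg4 (lubricin), Clic5 and Htra4 of the joint lining, held 4.55% (4.01 to 5.15) and 3.76% (3.36 to 4.20). With all variable genes in use, the Saa3-led state was sub-cluster 4, with 17 cells at day 0 and 1390 at day 5. It also carried Pi16, at 1245 CPM against 1081 CPM in all day 5 fibroblasts. Stromal cluster 2, with Pi16 among its leading genes, held 285 cells at day 0 and 1058 at day 5. The lower progenitor-like share thus does not show fewer cells with Pi16, and the larger share of sub-cluster 4 lowers the others. A cycling group with Mki67 and Top2a was sub-cluster 13, with 3 and 40 cells and a median of 31268 UMIs. A cluster held mostly by a single library may reflect that library and not a cell type. The progenitor-like share depended on the clustering and the doublet step: it was 21.1% at day 0 and 14.1% at day 5 with all variable genes in use, 18.11% and 16.5% at sub-clustering resolution 1.0, and 14.8% and 2.74% when no doublets were removed. The lining-like share was 2.41% and 1.64% under a stricter cell filter.

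**Figure D1:**
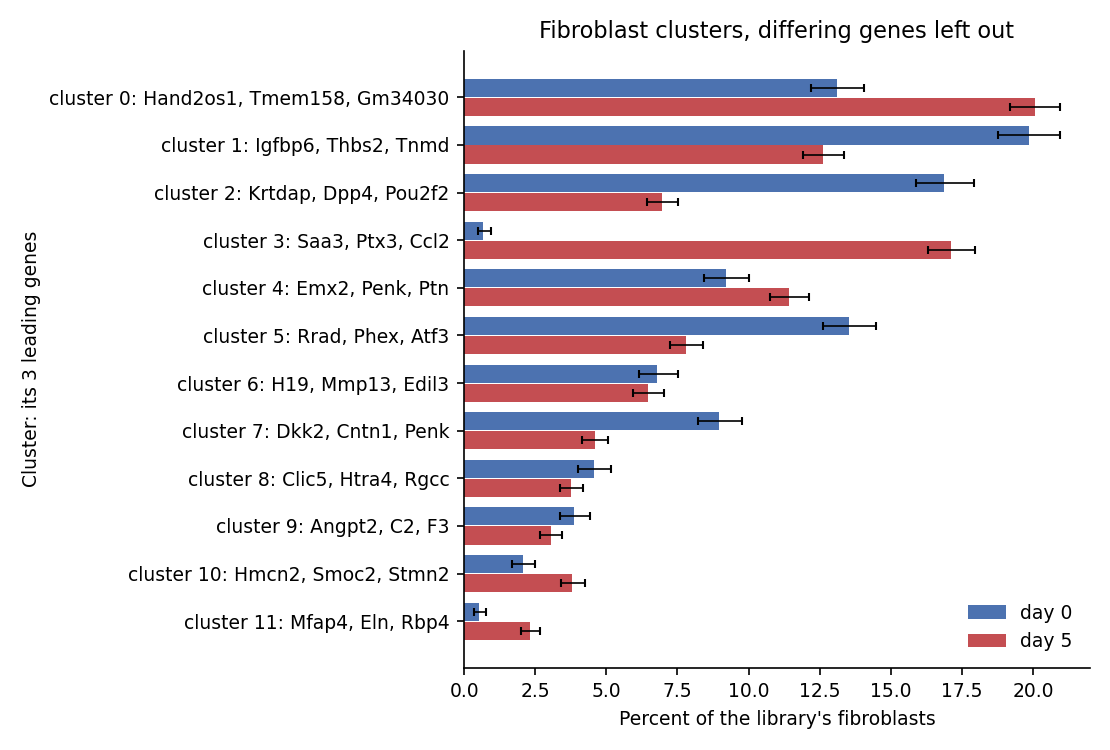
Share of each library's fibroblasts, in percent, in the 12 clusters formed without the genes that differ between the libraries, each labelled with its 3 leading genes. Bars are day 0 (blue) and day 5 (red), and error bars are 95% binomial intervals that cover counting error only. Cluster 3, led by Saa3, Ptx3 and Ccl2, stands at 0.680% at day 0 and 17.1% at day 5.

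Fibroblasts of the day 5 library carried far higher levels of RNA for acute-phase proteins, chemokines that draw myeloid cells, and matrix-remodelling factors. Saa3, which encodes an acute-phase serum amyloid A (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700 on mm10), stood at 4.10 CPM at day 0 and 658 CPM at day 5, 161-fold higher (141 to 184). It was the gene with the largest ratio among the 2714 that met the naming rule. Its relative Saa1 was 12.05-fold higher (10.9 to 13.4). The chemokine Cxcl5, which draws neutrophils, was 17.2-fold higher (15.4 to 19.3), and the monocyte chemokines Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) and Ccl7 were 7.72-fold (7.37 to 8.09) and 6.003-fold higher (5.81 to 6.20). The innate defence genes Ptx3 and Lcn2 were 7.85-fold (7.50 to 8.22) and 6.41-fold higher (6.17 to 6.65). From the list of matrix-degrading enzymes and inhibitors, the metalloproteinase Mmp3 was 5.50-fold higher (5.34 to 5.67), and the metalloproteinase inhibitor Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735) was 6.35-fold higher (6.18 to 6.52), with 708 CPM at day 5. Angptl4, an inhibitor of lipoprotein lipase, was 12.98-fold higher, the adhesion molecule gene Chl1 13.5-fold and the zinc transporter gene Slc39a14 5.59-fold.

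Much of this lay in sub-clusters 4 and 13, and whether the rest comes from other fibroblasts was left open by RNA of these sub-clusters in the other droplets. Without these sub-clusters, a choice made after the data were seen, 7 of the 12 genes were still at least 1.5-fold higher at day 5. Saa3 was then 11.8-fold higher (10.3 to 13.6), Angptl4 3.31-fold, Cxcl5 3.16-fold, Mmp3 1.87-fold, Saa1 1.73-fold, Ccl7 1.66-fold and Lcn2 1.65-fold. Chl1 was 1.47-fold, Ccl2 1.43-fold, Slc39a14 1.13-fold and Timp1 1.10-fold higher, and Ptx3 had a ratio of 0.920 (0.866 to 0.979). These values include any RNA of sub-clusters 4 and 13 in the other droplets, whose share was at most 3.78% (from Saa2). At that share it would give 187% of the Saa3 there, 125% of Chl1 and 114% of Ptx3, so the true share was lower. It would also give 67.9% of Cxcl5 and 32.0% of Mmp3. After its subtraction 1 of the 12 genes, Angptl4, was at least 1.5-fold higher, at 1.76-fold. Since the share is too large, 1 gene is a lower limit.

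Among genes that met the naming rule, which asks for at least 50 CPM in the higher library, the 12 with the lowest ratios in day 5 fibroblasts included a regulator of sterol supply and a cytoskeletal gene. Mir22hg, the host transcript of microRNA miR-22 (ENSMUSG00000085148, chromosome 11, 75461539 to 75466676), was 3.38-fold lower at day 5 (3.22 to 3.55). Tmem100 was 3.16-fold lower (3.07 to 3.25), from 272 to 85.9 CPM, and Filip1l was 2.99-fold lower. Tppp3, which promotes tubulin polymerization, was 2.75-fold lower, the matricellular gene Ccn3 2.71-fold and the LIM-domain gene Fhl1 2.56-fold. Insig1, which restrains sterol synthesis and is itself a target of the sterol regulator SREBP, was 2.42-fold lower (2.29 to 2.55). Scg3, Zfp385a, Efhd1, Engase and Usp2 were between 2.27-fold and 2.51-fold lower. Some of these lead clusters with a lower share at day 5, such as Scg3 and Efhd1, and part of their difference lies there. With sub-clusters weighted equally, the ratios were 0.574 for Scg3, 0.460 for Zfp385a, 0.580 for Efhd1, 0.563 for Engase and 0.485 for Usp2. Without sub-clusters 4 and 13, 19 of the 24 named genes kept a ratio of at least 1.5-fold in their direction, among them all 12 lower genes.

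**Figure D2:**
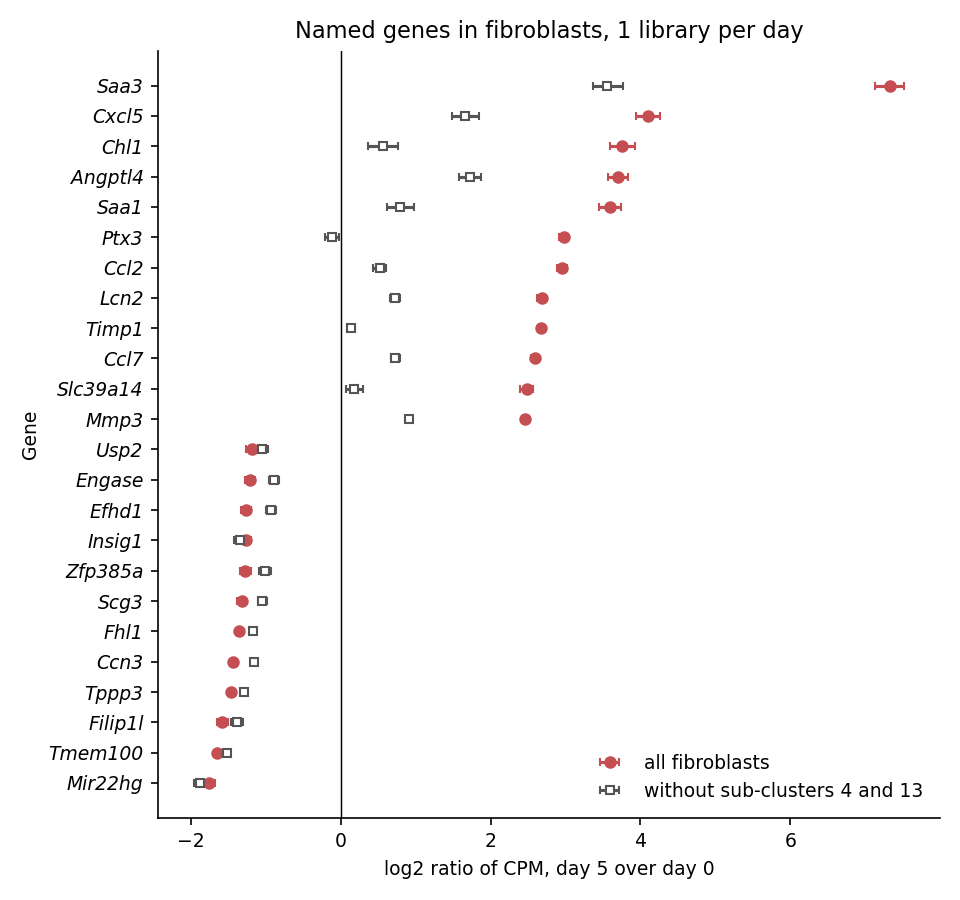
Log2 ratio of CPM, day 5 over day 0, for the 24 named genes in all fibroblasts (filled circles) and in fibroblasts without sub-clusters 4 and 13 (open squares), with 95% intervals that cover counting error only, 1 library per day. The inflammatory genes lie nearer 0 without these sub-clusters, with Saa3 at 11.8-fold in place of 161-fold, and the 12 lower genes stay at least 1.5-fold lower.

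The gene lists, fixed before the data were examined, place the day 5 fibroblasts higher for inflammation, complement, cell division and glycolysis, in large part through sub-clusters 4 and 13. Of 16 lists, 11 had a median log2 ratio above the central 95% of the medians of 10000 random lists matched in size and expression. The chemokine list had a median of 0.97 (100th percentile), with 9 of 17 measured members at least 1.5-fold higher and none lower. In it, Ccl20, which draws dendritic cells and T cells, had 0 UMIs at day 0 and 364 at day 5 and was at least 76.0-fold higher against the 3 counts that a 0 allows. Of cytokines and myeloid growth factors (median 0.36), 6 of 14 members were higher and 1 was lower. Tnfsf11, the osteoclast-inducing ligand RANKL, was 12.1-fold higher (8.58 to 17.5) at a low 7.68 CPM but 1.31-fold (0.839 to 2.09) without sub-clusters 4 and 13, Csf3 had 1 UMI at day 0 and 167 at day 5, and Tslp was 1.81-fold lower. Of NF-kB targets (median 0.49), 6 of 16 were higher, led by the superoxide dismutase gene Sod2 at 3.29-fold and Nfkb2 at 1.71-fold. Of complement genes (median 0.29), 4 of 14 were higher and 2 lower, with C1qtnf3 at 1.73-fold higher and the complement inhibitor gene Cd55 at 1.99-fold lower. Of interferon response genes (median 0.22), 4 of 20 were higher, among them Oasl2 at 1.72-fold and Bst2 at 1.65-fold. Of proliferation genes (median 1.58), 11 of 16 were higher, such as Ube2c at 9.94-fold and Cenpf at 6.59-fold. Of glycolysis and hypoxia genes (median 0.29), 2 of 18 were higher, Hif1a at 1.74-fold and Pfkl at 1.67-fold. The list of stress genes that tissue digestion can induce was also higher, with a median of 0.21, 1 of 19 members at least 1.5-fold higher (Ier3, 1.70-fold) and 2 lower. The number of lists above that range was 7 with cells thinned to equal depth, 6 without sub-clusters 4 and 13, and 5 with sub-clusters weighted equally. Without sub-clusters 4 and 13, the medians of the chemokine, NF-kB and stress lists were 0.56, 0.21 and 0.32, and those of the cytokine, glycolysis and proliferation lists were -0.19, -0.19 and -0.0035. The complement median was then 0.16, at the 96.71th percentile and so within the range of random lists, with 2 members higher and 3 lower.

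Matrix and signalling genes went both ways in day 5 fibroblasts. Of matrix-degrading enzymes and inhibitors (median 0.23), 5 of 16 measured members were higher and none lower, and Timp3 was 1.40-fold lower. Of extracellular matrix genes (median 0.12), 4 of 21 were higher and 1 lower. The injury-associated matrix genes Tnc and Cthrc1 were 4.88-fold and 2.88-fold higher, and the collagen crosslinking enzyme gene Loxl2 was 1.73-fold lower. At day 5, Tnc stood at 96.1 CPM in sub-clusters 4 and 13 and 5.25 CPM in the other fibroblasts, and Cthrc1 at 95.5 and 10.6 CPM. Without these sub-clusters 1 of the 21 matrix genes was higher and 4 were lower. The TGF-beta and BMP list had a median of -0.11 (8.64th percentile), with 5 of 18 members higher and 2 lower. In it the ligand gene Tgfb2 was 1.88-fold lower, the receptor gene Tgfbr2 1.51-fold lower and Ltbp2 3.41-fold higher. Wnt antagonists and bone regulators (median 0.05) split, with Sfrp2 2.83-fold higher and Sfrp4 2.11-fold lower. On the Notch list (median -0.04) the target Hes1 was 1.91-fold lower and Notch1 was 1.75-fold higher. Of the CD200 and DKK3 fibroblast markers (median 0.02), Cd200, a ligand that restrains myeloid cells, was 1.78-fold lower, and Pdpn, which encodes podoplanin, was 1.66-fold higher. Antigen presentation (median 0.07) had 1 of 10 members higher, and adipogenic and lipid handling genes (median 0.26) had 1 of 12, Fabp4 at 2.20-fold. The signs of the matrix, Wnt, and CD200 and DKK3 medians turned without sub-clusters 4 and 13, to -0.29, -0.30 and -0.40, and the Notch median turned to 0.08.

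**Figure D3:**
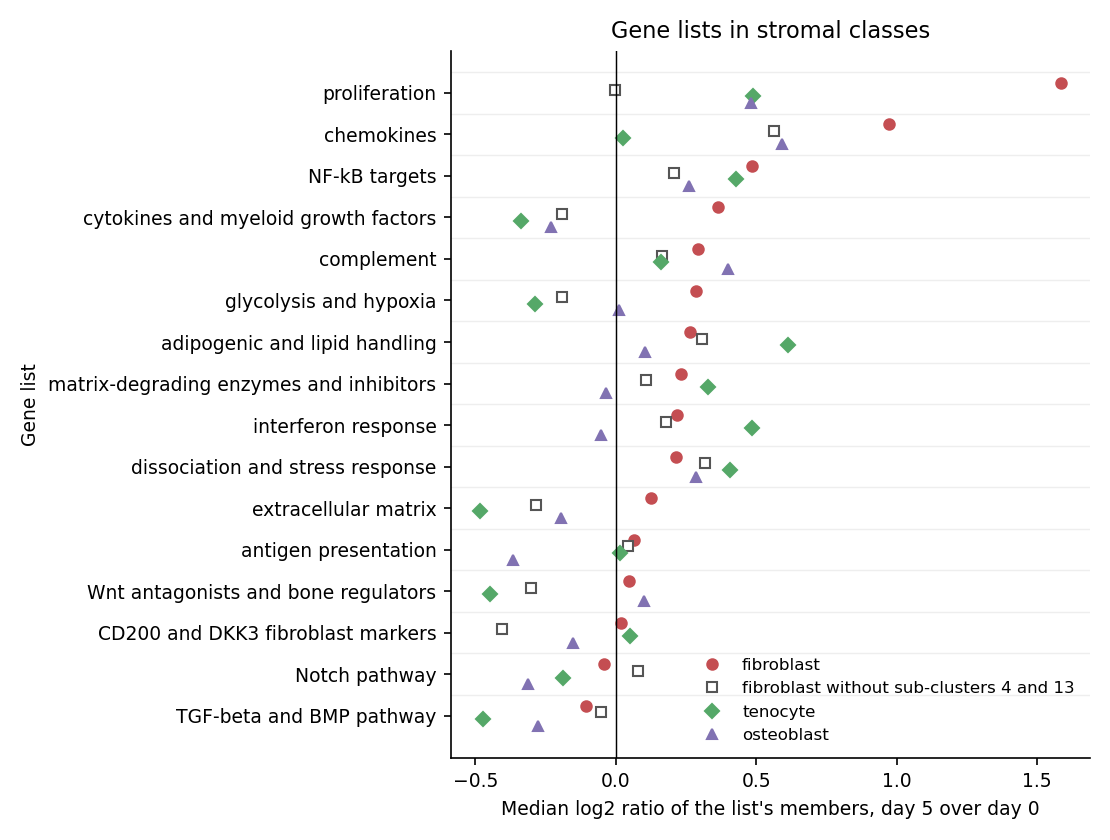
Median log2 ratio of CPM, day 5 over day 0, of the 16 gene lists in all fibroblasts, in fibroblasts without sub-clusters 4 and 13, in tenocytes and in osteoblasts, with 1 library per day. The chemokine list stands at 0.97 in all fibroblasts and 0.56 without the sub-clusters, and the extracellular matrix list stands at 0.12 and -0.29.

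Lining-like fibroblasts, which face the joint space, held more UMIs of acute-phase and protease genes at day 5 too, with no background of other fibroblasts subtracted. In this sub-cluster (310 cells at day 0, 376 at day 5), Saa3 was 84.5-fold higher at day 5 (42.6 to 196), the protease inhibitor gene Slpi 6.29-fold (4.57 to 8.84), Mmp3 3.47-fold, Ccl2 2.96-fold and Timp1 2.40-fold. Insig1 was 3.48-fold lower (2.92 to 4.18), the sterol synthesis gene Fdps 2.65-fold, and the chemokine scavenger receptor gene Ackr3 2.27-fold. The lists of matrix-degrading enzymes (median 0.42, 7 of 16 members higher), NF-kB targets (0.33, 7 of 16) and complement (0.33, 2 of 9) were at or above the 99.9th percentile. So was the stress list, with a median of 0.24, no member at least 1.5-fold higher and 2 lower. Glycolysis and hypoxia had a median of -0.27 (0.0500th percentile), with 2 of 18 members lower, Vegfa at 1.74-fold and Bnip3 at 1.55-fold, and 1 higher. In fibroblasts outside the lining-like sub-cluster, the same 5 genes as in all fibroblasts had the largest ratios among those that met the naming rule, led by Saa3 at 159.9-fold and Cxcl5 at 16.7-fold. Slpi, under the 50 CPM of that rule, had 0 UMIs at day 0 and 2152 at day 5 there. Most of these lay in sub-clusters 4 and 13, where Slpi stood at 92.9 CPM at day 5. All other day 5 fibroblasts held 330 UMIs of Slpi, 298 of them in the lining-like cells. Tmem100 was lowest among the genes of the rule, at 3.52-fold lower. It had a ratio of 0.902 in the lining-like cells.

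Tenocytes of the day 5 library (1102 cells against 899) carried more protease and interferon transcripts and fewer transcripts of matrix and of TGF-beta and BMP signalling. Mmp3 was 6.51-fold higher (5.40 to 7.90), the microfibril gene Mfap2 3.78-fold (3.22 to 4.45), the acute-phase gene Serpina3n 3.70-fold and the chemokine Ccl19 3.51-fold. Nrep was 5.20-fold lower (4.70 to 5.75), the phosphatase gene Dusp8 5.15-fold, Tppp3 4.49-fold, the TWEAK receptor gene Tnfrsf12a 3.84-fold and Slurp1 3.84-fold. Of extracellular matrix genes (median -0.48), 8 of 21 were lower and 1 was higher, with Loxl2 2.46-fold lower and Col5a1 2.29-fold lower. Of TGF-beta and BMP genes (median -0.47), 6 of 17 were lower and 2 higher, with Chrdl1 1.82-fold higher and, among the lower, Ltbp2 at 2.17-fold and Inhba at 1.98-fold. The medians of the adipogenic (0.61, 5 of 9 members higher, Lpl 2.43-fold and Apoe 1.95-fold), interferon (0.48, 6 of 16 higher and 1 lower, Ifit1 3.02-fold and Bst2 2.61-fold) and NF-kB (0.43) lists were above 0. The complement median (0.16) lay within the range of random lists (95.4th percentile), with 3 of 11 members higher and 2 lower. The stress list stood at 0.41, with 7 of 19 members higher and 2 lower. The chemokine list was near 0 (0.03), and Ccl2, much higher in fibroblasts, was 2.02-fold lower here. Medians of the other lists were 0.33 for matrix-degrading enzymes, with Mmp13 21.7-fold higher, 0.49 for proliferation, 0.05 for CD200 and DKK3 markers, 0.01 for antigen presentation, -0.19 for Notch, -0.29 for glycolysis, -0.34 for cytokines and -0.45 for Wnt antagonists. Cluster 11 held a larger part of the tenocytes at day 5, so clusters 3 and 11 were also compared each on its own, a choice made after the data were seen. The medians in clusters 3 and 11 were -0.59 and -0.21 for extracellular matrix, -0.42 and -0.41 for TGF-beta and BMP, 0.32 and 0.51 for interferon, and 0.06 and 0.87 for chemokines. For the stress list they were 0.56 and 0.70, above the median over both clusters. Of its 19 members, 9 were higher and 1 lower in cluster 3, and 11 higher and 0 lower in cluster 11. Mmp3 was 2.50-fold higher in cluster 3 and 16.2-fold in cluster 11, and Nrep was 6.11-fold and 4.72-fold lower. Slurp1, a leading gene of cluster 3, was 2.76-fold lower there and had 11 and 12 UMIs in cluster 11.

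Osteoblasts of the day 5 library (588 cells against 542) held more UMIs of acute-phase and monocyte chemokine genes and fewer of the sterol regulator Insig1. Fibroblast RNA in these droplets was not excluded as a source of Saa3, Ptx3, Ccl2 and Ccl7, which were seen in 6.29%, 7.99%, 5.10% and 4.93% of the day 5 osteoblasts. Saa3 was 93.7-fold higher from 5 UMIs at day 0 (39.9 to 290), Angptl4 4.44-fold (3.47 to 5.74), Ptx3 3.57-fold, Col11a2 2.86-fold and the osteoblast gene Ifitm5 2.56-fold. Insig1 was 2.96-fold lower (2.47 to 3.57), Angptl2 2.81-fold, the neuropeptide gene Npy 2.65-fold and Mir22hg 2.52-fold. Of 11 measured chemokines (median 0.59), 6 were higher, such as Ccl7 at 6.46-fold and Ccl2 at 6.26-fold, and 2 were lower. Of complement genes (median 0.40), 3 of 10 were higher, with Cfb at 2.95-fold and C3 at 2.80-fold. The medians of TGF-beta and BMP genes (-0.28, 2 of 17 lower and 1 higher, Chrdl1 at 1.90-fold) and of extracellular matrix genes (-0.19, 4 of 21 lower, such as Col6a3 at 1.68-fold and Col5a3 at 1.62-fold, and Eln 2.94-fold higher) were under 0, and Timp1 was 1.75-fold lower. The osteoclast growth factor gene Csf1 was 1.60-fold lower and Tnfsf11 1.41-fold lower, from 31.9 to 22.6 CPM. The other medians were 0.48 for proliferation, 0.28 for stress genes, 0.26 for NF-kB targets, 0.10 for adipogenic genes, 0.10 for Wnt antagonists, 0.01 for glycolysis, -0.03 for matrix-degrading enzymes, -0.05 for interferon response, -0.15 for CD200 and DKK3 markers, -0.23 for cytokines, -0.31 for Notch and -0.37 for antigen presentation.

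Vessel cells were few. In blood endothelial-like cells (85 and 36 cells) the activation list had a median of 1.67, with the leukocyte adhesion gene Sele 6.72-fold higher and Csf3 at 0 UMIs at day 0 and 88 at day 5. A single day 5 droplet with 29771 UMIs held 594 of the 938 counts of this list, with 116 of the 133 of Sele and 86 of the 88 of Csf3, and the median without it was -0.37. These values thus describe that droplet and not the class. The angiogenesis list had a median of -0.29, within the range of random lists (2.65th percentile), with 2 of 10 members lower, the tip-cell gene Esm1 at 2.07-fold and Dll4 at 1.69-fold, and 2 higher, among them Col4a1 at 1.58-fold. In mural-like cells (15 and 19 cells) the contractile list had a median of 1.05, with 7 of 9 members higher, led by Acta2 at 3.98-fold and Tagln at 3.68-fold, and other scalings shifted all genes of this class by up to 0.22.

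RNA of macrophages was low in the fibroblasts. The macrophage genes C1qa and Cd74 stood at 0.0728 and 0.637 CPM at day 0 and 0.0684 and 0.650 CPM at day 5, against 974 and 3772 CPM in the myeloid library. Of the keratinocyte genes, Krt5 and Krt14 had 0 counts, and Krt10 stood at 32.99 CPM in 26.7% of day 0 fibroblasts and 22.8 CPM in 19.8% at day 5. Red cell genes were higher at day 5 but lay in few droplets, since 2 fibroblast droplets held 97.9% of 14111 counts and 1 tenocyte droplet held 99.7% of 10893. The neutrophil genes S100a8 and S100a9 had 1739 counts in day 5 fibroblasts, of which 1558 lay in 1 droplet. Camp, on the same list, stood at 0.400 CPM at day 0 and 4.51 CPM at day 5, in 2.86% of the day 5 cells. Muscle genes were at most 4.11 CPM at day 0 (Tnnt3).

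The myeloid library describes leukocytes of the paw sorted for CD11b and against Ly6G at day 9, and has no counterpart on another day. Its shares are of sorted cells and not of the leukocytes of the paw. Macrophage-like cells were 56.3% of its 5555 cells (54.98 to 57.6), osteoclast-lineage-like cells with Acp5, Ctsk and Mmp9 were 13.3% (12.4 to 14.2), dendritic-like cells 10.999% (10.2 to 11.9) and monocyte-like cells 7.11% (6.45 to 7.82). Among the macrophages, 18.54% of all cells were of the Arg1-positive infiltrating type and 3.37% of the interstitial type that carries Lyve1, Cd163 and the RELM-alpha gene Retnla. The rest fell into clusters 1 (462 cells, led by Thbs1, Il1b and Cxcl2), 2 (452, led by Vsig4, Folr2 and Gpr34), 4 (438, led by Tppp3 and Cd36), 5 (431, led by Ms4a7, Aif1 and Apoe) and 13 (127, led by the interferon genes Rsad2 and Ifit1). Lymphoid-like cells made up 4.16%, erythroid 1.55%, neutrophil-like 1.44% and basophil-like 0.450%. Unnamed cycling cells, led by Ube2c and Cdk1, made up 3.67%, and 58 cells, or 1.04%, were of endothelial-like or fibroblast-like CD45-negative kinds. Cluster 3, the larger dendritic-like cluster, had 4 markers of the MHC class II macrophage list and 1 of its own among the 10 genes that lead it against cells of other classes. Monocyte-like cluster 7 had 2 markers of its own and 2 of the Arg1-positive type among its leading genes. The mitochondrial limit removed 21.2% of day 9 barcodes, against 4.41% and 5.35% in the stromal libraries. The macrophage share was 65.0% at a lower clustering resolution.

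Myeloid classes at day 9 differed in inflammatory, repair, lipid and antigen presentation genes. The classes of at least 100 cells compared here include monocytes, dendritic-like and osteoclast-lineage cells, not macrophages alone. Of 60 genes on 4 fixed macrophage lists, 54 differed at least 5-fold between them. For Nos2, Il23a and Alox15 this rests on low counts, at most 6, 29 and 10 in the class of the highest level. Medians of the inflammatory and the repair list, each set against the median of the classes, had opposite signs in most classes: 1.83 and -0.48 in cluster 1, -0.96 and 0.82 in cluster 2, -0.54 and 0.26 in RELM-alpha macrophages, 0.87 and -0.16 in cluster 13, and 0.78 and -1.63 in monocytes. In clusters 4 and 5 the inflammatory median was near 0 (-0.05 and -0.07) and the repair median was 0.69 and 0.37. Signs were the same in Arg1-positive cells (0.88 and 0.35), dendritic-like cells (-0.10 and -0.46) and osteoclast-lineage cells (-2.82 and -1.41). These classes were formed from the same counts, so the genes that lead a cluster are no separate finding. Osteoclast-lineage cells, 13.3% of the cells, held 16165372 of the 53641290 UMIs of the kept cells, so levels across all cells give them more weight. Across all cells the inflammatory mediators of the highest level were Cxcl2 at 2025 CPM, Il1b at 1014 and Ccl4 at 352. Cluster 1 was highest for 9 of the 15 members of this list, such as Tnf at 665 CPM (636 to 694) and the prostaglandin synthase gene Ptgs2 at 1053 CPM, and osteoclast-lineage cells were lowest for most, with Tnf at 20.3 CPM. Of 15 pro-resolving and repair genes, the RELM-alpha macrophages were highest for 6, among them the growth factor gene Igf1 at 245.5 CPM (214 to 281), Alox5 at 244 CPM and Pdgfc at 70.8 CPM. Cluster 1 was highest for 4, among them Vegfa at 365 CPM and Il10 at 26.7 CPM. Of 17 efferocytosis and lipid genes, 5 were highest in Arg1-positive cells and 4 in cluster 2. The genes of highest level were Apoe at 2384 CPM over all cells, Spp1 at 2266 and Lgals3 at 1673. Trem2 reached 948 CPM and the phosphatidylserine receptor gene Timd4 79.0 CPM in cluster 2, and Mertk reached 84.5 CPM in RELM-alpha macrophages. Of 13 antigen presentation genes, conventional dendritic-like cells (clusters 3 and 17) were highest for 8, with the co-stimulatory gene Cd86 at 299 CPM. Markers of the MHC class II macrophage list also led cluster 3 against cells of other classes, so its dendritic-like name is uncertain on these genes. Cluster 5 had the highest median of the macrophage clusters.

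**Figure D4:**
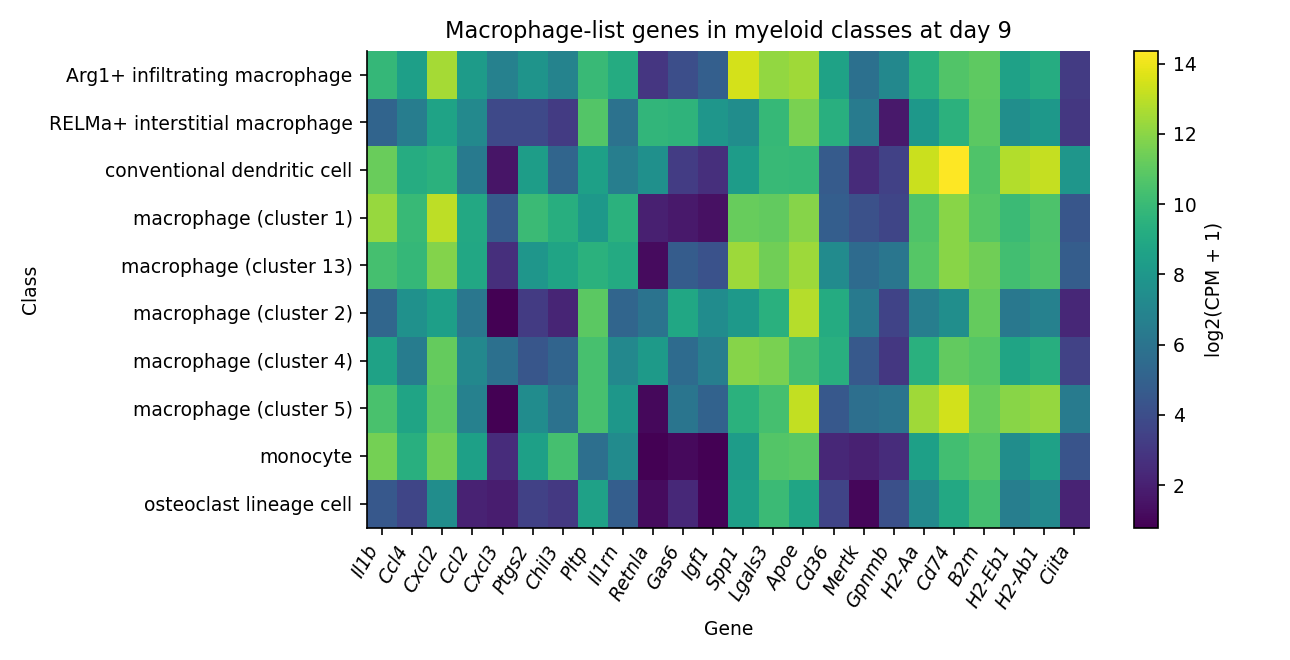
Level of macrophage-list genes, as log2(CPM + 1) by colour, in the myeloid classes of at least 100 cells at day 9, a single library. For each of 4 lists the plot shows the 3 members of the highest level over all cells. It also shows the 3 with the largest fold between classes among the rest. Some of these genes lead or name clusters shown, among them Il1b, Cxcl2, Spp1, Apoe, Cd36 and Retnla. Il1b stands at 4975 CPM in cluster 1 and 22.1 CPM in osteoclast-lineage cells.

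Ligands and receptors of 28 fixed pairs were set side by side to look at how fibroblasts and myeloid cells could address each other, with fibroblasts at days 0 and 5 and myeloid cells at day 9. No score of interaction was computed. Levels over all myeloid cells are of summed UMIs, in which osteoclast-lineage cells weigh more than by their number. Of 26 fibroblast genes, 6 were at least 1.5-fold higher at day 5: Tnfsf11, Ccl2, Ccl7, the efferocytosis bridge Gas6 at 1.88-fold, Il6 at 1.59-fold and C3 at 1.52-fold. Without sub-clusters 4 and 13 this number was 2, and Il6 had a ratio of 0.721. Their partners at day 9 were Ccr2 at 303 CPM over all cells and 1182 CPM in monocytes, Tnfrsf11a at 102 CPM and 155 CPM in osteoclast-lineage cells, Axl at 54.9 CPM, Il6ra at 98.9 CPM and C3ar1 at 211 CPM. The macrophage growth factor gene Csf1 was 1.23-fold lower at day 5, with 171 CPM, and its receptor gene Csf1r stood at 565 CPM at day 9. Cxcl12 was the fibroblast ligand of the highest level, with 2483 CPM at day 0 and 2896 at day 5, and its receptor gene Cxcr4 stood at 184 CPM. Cd200 was lower at day 5, and its receptor gene Cd200r1 stood at 22.2 CPM at day 9. In the other direction, Il1b, Tnf and Osm stood at 1014, 152 and 231 CPM in myeloid cells. Their receptor genes in day 5 fibroblasts stood at 154 CPM for Il1r1, 129 CPM for Tnfrsf1a and 69.9 CPM for Osmr. Spp1, at 2266 CPM, faced Cd44 at 98.2 CPM, and Apoe, at 2384 CPM, faced Lrp1 at 1237 CPM. Pdgfra and Pdgfrb stood at 397 and 105 CPM in day 5 fibroblasts, and Tgfbr2 was lower there.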

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

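Except for the tests of UMIs per cell, of the tenocyte clusters and of other cells in the endothelial droplet, the tests in this part were chosen after the result was seen.

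Inflammatory genes were higher in day 5 fibroblasts, led by Saa3, Cxcl5 and Chl1. RNA of leukocytes, at the amount that leukocyte-only genes allow, gives at most 0.231% of the day 5 level of any of the 12 genes (Lcn2). This argues against leukocyte RNA of the profile measured at day 9. That profile is from the library sorted against Ly6G, with 80 neutrophil-like cells, and leukocytes of day 5 may carry other levels of these genes. Stress from digestion stays open as a part of the difference, since the stress list, too, was above random lists, with a median of 0.32 in fibroblasts outside sub-clusters 4 and 13. In the other fibroblasts 7 of 12 genes were at least 1.5-fold higher. Once RNA of sub-clusters 4 and 13 was subtracted, at the largest share that Saa2 allows, 1 of 12 genes, Angptl4, was still so. That share would give 187% of the Saa3 seen there, so it is too large, and 1 gene is a lower limit. The test thus cannot decide whether sub-clusters 4 and 13 alone are the source. A response of fibroblasts to arthritis may be a source, but day and library cannot be told apart with 1 library per day.

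Extracellular matrix genes were lower at day 5 in tenocytes and osteoblasts, and in fibroblasts once sub-clusters 4 and 13 were left out. These sub-clusters held 17 and 3 cells at day 0 and 1390 and 40 at day 5, so this step takes away nearly only day 5 cells. Over all fibroblasts the median was 0.12, so the lower fibroblast value holds only outside these sub-clusters. If a few genes had taken a larger share of the counts, all other genes would be lower alike. The list median minus the median of random lists was -0.21 in osteoblasts, the nearest to 0 of these 3 classes, which argues against it. With cells thinned to equal depth the nearest median was -0.30, which argues against UMIs per cell. A different mix of clusters is not the whole cause in tenocytes, since the median was -0.59 and -0.21 within clusters 3 and 11. With fibroblast sub-clusters weighted equally it was -0.18, which argues against a different mix of the sub-clusters used there. That weighting leaves out fibroblast sub-clusters 4, 11 and 13, most of whose cells were from day 5, so it cannot speak for all fibroblasts. A lower matrix programme at day 5 may be the source, and library preparation stays open. Stress from digestion was not tested for this result.

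Endothelial activation genes were higher in day 5 blood endothelial-like cells, with a median of 1.67. Without the droplet of the most UMIs the median was -0.37, so this droplet carries the result. Markers of fibroblasts, tenocytes, osteoblasts, mural cells, macrophages and neutrophils in it reached at most 0.900% of their level in that class (mural cells). This argues against cells of these classes in the droplet, but a second endothelial cell could not be seen this way. The droplet may hold an activated endothelial cell of high RNA content, and nothing about the class can be said from it.

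Opposite signs between classes drew attention to these results, and the differences were not tested. The extracellular matrix median was 0.12 in fibroblasts, -0.48 in tenocytes and -0.19 in osteoblasts. The glycolysis and hypoxia median was 0.29 in fibroblasts and -0.29 in tenocytes, and it was -0.27 in lining-like fibroblasts and 0.32 in the other fibroblasts. Without sub-clusters 4 and 13 the fibroblast medians were -0.29 for extracellular matrix and -0.19 for glycolysis, the same sign as in tenocytes. Leaving these sub-clusters out takes away nearly only day 5 cells, so this cannot settle whether the classes differ.

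The myeloid library held 25 fibroblast-like cells that the gate should have removed, and 4 of the 12 genes were seen there in at least 5 cells, with intervals above both the level that 3 counts give (10.98 CPM) and the other cells of the library. These were Angptl4 at 87.9 CPM, Ccl2 at 183 CPM, Timp1 at 582 CPM and Slc39a14 at 183 CPM, against 2.62, 129, 63.9 and 38.7 CPM in the other cells. Single cells held 13 of 24, 28 of 50, 62 of 159 and 32 of 50 of these counts, and Ptprc and Cd74 stood at 187 and 1428 CPM in the same droplets. Other genes of the 12 lay above these levels in fewer cells, such as Cxcl5, with all 123 counts in 1 cell, and Saa3, with 21 of 26.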

How the results depend on the processing

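Clustering without differing genes, and fibroblasts without sub-clusters 4 and 13 or with sub-cluster 12, were alternatives chosen after seeing the data. Of 544 gene ratios under alternatives, 405 stayed within their counting interval, 138 moved in the same direction and 1 reversed. Of 219 list medians, 174 stayed, 23 moved and 22 reversed, and of 130 ligand and receptor ratios, 83, 38 and 9. Of 194 myeloid folds, 86 stayed and 108 moved, and none reversed. Median-of-ratios and TMM scaling moved none of the values given, and shifted the median of all genes by over 0.1 only in mural-like cells (0.22 and 0.20). Few cells limit the endothelial and mural values. The stricter filter left no monocyte class. Thinning left out 41 and 90 fibroblasts. The cause was not tested for the values below, except where an alternative leaves out the cells in question.

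The fibroblast share at day 0 was 75.2% under the stricter filter. At day 5 it was 82.6% with the looser filter, 80.65% with the stricter, 82.4% with no doublets removed, 82.7% at resolution 0.5 and 83.3% with each library clustered alone. The lining-like share was lower at day 5 under each of these: 2.81% and 2.02% (looser), 2.41% and 1.64% (stricter), 4.34% and 3.56% (no doublets removed), 5.095% and 1.93% (each library alone), and 4.55% and 3.76% (without differing genes). The progenitor-like share was 31.4% and 23.98% (stricter), 14.8% and 2.74% (no doublets removed), 18.11% and 16.5% (sub-clustering resolution 1.0) and 16.9% and 6.97% (without differing genes), and 17.2% at day 5 with each library alone. The sub-cluster 4 share at day 0 was 0.650% with no doublets removed, 0 with each library alone and 0.680% without differing genes. At day 5 it was 18.14% (stricter), 18.65% (no doublets removed) and 21.4% (each library alone). The macrophage share was 62.9% (stricter), 57.7% (no doublets removed) and 65.04% (resolution 0.5).

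Without sub-clusters 4 and 13, 6 lists lay above the range of random lists and 2 of the 26 ligands and receptors were 1.5-fold higher. Medians then turned sign for cytokines (-0.19), extracellular matrix (-0.29), Wnt antagonists (-0.30), CD200 and DKK3 markers (-0.40), glycolysis (-0.19), proliferation (-0.0035) and Notch (0.080). Ratios turned for Ptx3 (0.920), Il1r1 (0.996), Cd44 (0.730), Il6 (0.721), Tnfrsf1a (0.869), Cx3cl1 (0.881) and Il33 (0.807). With sub-clusters weighted equally, 5 lists lay above, and medians turned for cytokines (-0.12), extracellular matrix (-0.18), Wnt antagonists (-0.28), CD200 and DKK3 markers (-0.34), glycolysis (-0.13) and proliferation (-0.12). With cells thinned to 2000 UMIs, 7 lists lay above, and medians turned for cytokines (-0.028), antigen presentation (-0.025), extracellular matrix (-0.016) and Notch (0.015). With the mean of each cell's CPM, extracellular matrix turned to -0.028, Tnfrsf1a to 0.997 and Cx3cl1 to 0.9996. The stricter filter turned Wnt antagonists to -0.13 and Cx3cl1 to 0.987. The endothelial activation median turned to -0.66 (looser), -0.83 (stricter) and -0.39 (cells without Ptprc, S100a8 and S100a9).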

Other observations

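The sterol and clock gene lists in this part were added after the data were seen, and their tests were set out before the list values were seen. The tests of fibroblast RNA in other droplets were chosen after the result was seen.

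Insig1 and Fdps, targets of the sterol regulator SREBP, were among the genes named as lower at day 5 in some stromal classes. A list of 19 further sterol genes, such as Hmgcs1, Sqle and Cyp51, none of them named in the comparisons, had medians of -0.23 in fibroblasts, -0.53 in tenocytes and -0.68 in osteoblasts, with 3, 9 and 10 members at least 1.5-fold lower and none higher. The highest percentile among random lists over the 3 classes was 0.0600. Without sub-clusters 4 and 13 the list stood at -0.57 in fibroblasts. A lower activity of SREBP in day 5 stromal cells may explain this, as a hypothesis found and tested on the same 2 libraries.

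Usp2, a clock-controlled gene, was 2.27-fold lower in day 5 fibroblasts, so a different time of day for the 2 libraries was tested. The median log2 ratio of 9 clock output genes was -0.11 in fibroblasts, 0.17 in tenocytes and -0.32 in osteoblasts, and that of 5 genes of the opposite phase was -0.24, -0.57 and -0.10. The test, as set out, asked for medians beyond 0.3 in opposite directions in all 3 classes, which was not seen. In tenocytes the medians had opposite signs, at the 93.5th and 0.12th percentiles of random lists. In fibroblasts and in osteoblasts both medians were under 0. A smaller shift is not excluded.

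Some inflammatory genes were higher at day 5 in osteoblast-like cells (Saa3, Angptl4, Ptx3, Ccl2 and Ccl7) and in tenocyte-like cells (Mmp3, Serpina3n and Ccl19), and RNA of fibroblasts in these droplets could be a source. Its share was bounded by the upper limit of the fibroblast gene lowest in each class relative to fibroblasts, the tested genes left out. In osteoblasts that gene was Pi16. With the profile of all day 5 fibroblasts, the share could give up to 46.6% of the day 5 level of Ccl2, 30.6% of Ccl7, 21.1% of Saa3, 13.4% of Ptx3 and 5.14% of Angptl4. With that of sub-cluster 4 it could give up to 134% of Ccl2, 82.9% of Ccl7, 69.9% of Saa3, 42.7% of Ptx3 and 13.9% of Angptl4, so fibroblast RNA is not excluded there. In tenocytes it could give up to 11.6% of Ccl19, 9.15% of Mmp3 and 6.08% of Serpina3n, which leaves a part open.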
